A study of Mus musculus with 2 samples.

How the data were processed

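H3K4me1 was measured by chromatin immunoprecipitation and sequencing in neural tube of mouse embryos (B6NCrl, embryonic day 12.5, both sexes pooled), in 2 biological replicates of 120 and 88 embryos, per the labels. The labels also give a size range of 300 to 500 with no unit. Both samples belong to 1 group and no other group was present.

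The authors deposited 4 peak lists. Per the text files deposited with them, the peaks of replicate 1 were called on its alignment, which joins 2 technical replicates, against 2 control alignments, and those of replicate 2 against 1 control alignment. The pooled list was called on both alignments together, and the replicated list was derived from the pooled list and the 2 single lists, per the same text files. The lists themselves do not bear out a rule that needs a peak in both single lists, as 14863 replicated peaks lack one at an overlap of 1 bp, so other lists not used here may have entered. The genome was mm10, per the same text files. The peak caller, the aligner, their versions and the overlap rule of the replicated list are not given in the sources used here. The fold of a peak is the ratio of its signal to the control as deposited by the authors. The significance of each peak was deposited by the authors as −log10 of p and of q, and the lowest deposited −log10 p was 2.00 in replicate 2 and 2.01 in replicate 1. The deposited position of the summit in each peak was used to place the peak. These values were used only to describe, rank or filter peaks within a list. Read numbers are not in the peak lists, so the depth per sample is unknown and no counting interval is given. Replicate 1 and replicate 2 may differ in depth, which affects how many weak peaks each list holds.

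Coordinates were compared with the mm10 sequence. No peak lay beyond the end of a chromosome, and 1 of 212809 pooled peaks lay off the main chromosomes and was left out. Genes were the 21851 protein-coding genes of GENCODE vM21, with 1 TSS per gene for gene windows, promoter profiles and domains. The classes of summits and the peaks beyond 5 kb of a TSS used the TSS of all protein-coding transcripts tagged basic. Of these, 20862 symbols were also in the RefSeq annotation, 99.97% of them at an overlapping place. All positions are 1-based. Analyses were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

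Peaks of the replicates were called shared at an overlap of at least 1 bp and set beside 100 random placements on the same chromosomes. Summits were assigned to 1 class each, in the order promoter (within 1000 bp of a TSS), within 5000 bp of a TSS, other exon, intron, and outside protein-coding genes, and shares were set beside those of the genome without N bases. Coverage of TSS was measured in steps of 100 bp up to 5000 bp. A promoter was CpG-rich if the 500 bp on each side of the TSS had a GC content of at least 50% and an observed to expected CpG ratio of at least 0.6.

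For each gene the percent of the window of 50000 bp on each side of the TSS covered by peaks was computed. The median of each gene list was placed among 10000 random lists of the same size, matched in 5 bins on the number of TSS in the window, and called above at the 97.5th percentile or higher and below at the 2.5th or lower. The lists were fixed before the data were examined: neural progenitors, ventral patterning, dorsal patterning, spinal neuron subtypes, pan-neuronal genes, forebrain regulators, later glia, retinoic acid and Hox cofactors, neural crest and sensory ganglia, paraxial mesoderm and mesenchyme, skeletal muscle, endothelium, blood and microglia, liver, heart, stratified epithelium, germ line, housekeeping, 3 groups of Hox genes, and the Sox, Pax, Fox, LIM homeobox, Wnt, olfactory receptor, vomeronasal receptor and ribosomal protein families. The procedure was tested on simulated data of 20000 genes. Of 200 lists of 15 genes with no difference 5% were called, and of 200 lists raised 2.5-fold 99% were called above. The simulated values were independent between genes and included none without coverage. In the data neighbouring genes share parts of their windows and some genes have no peak, so these rates need not carry over.

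Genes were named by a rule fixed before the data were examined: in each symbol list and Hox group the 3 members with the highest coverage and the 1 with the lowest, the genes with a TSS in or else nearest to the 10 longest domains, and any Hox gene. Domains were made by merging replicated peaks within 1000 bp, and the 500 longest were compared with all genes. Consensus sequences were counted on both strands in peaks and in 1 random interval per peak of the same length and chromosome, outside pooled peaks, with GC content within 2 percentage points. An interval was found for 98.8% of the replicated peaks.

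With 2 replicates of 1 group no p-value is given. Values are those of the replicated list, with the mean ± SD of the replicates' own lists (n = 2), whose peaks are shorter, so that the mean of the replicates can lie below the replicated value. The alternatives were stricter thresholds (−log10 q of at least 2 or 5, or the 50000 peaks with the highest −log10 p), the pooled list, other overlap rules, windows, distances, matchings and merging distances, flanking sequence in place of matched intervals, and leaving out each replicate. Leaving out a replicate means using the other replicate's own peak list in place of the replicated list, so that the kind of list changes along with the replicate. Added after seeing the data were replicated peaks with a peak in both replicates, matching on the promoter's CpG class, autosomal genes only, motif counts in peaks beyond 5 kb of a TSS, and the chromosome densities without each replicate.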

Results

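Chromatin immunoprecipitation followed by sequencing was used to map histone H3 monomethylated at lysine 4 (H3K4me1), a mark found at enhancers and on the flanks of promoters, in mouse neural tube, the embryonic structure that forms the brain and spinal cord. The tissue came from embryos of strain B6NCrl at embryonic day 12.5, with both sexes pooled. A single group was sampled in 2 biological replicates, of 120 embryos for replicate 1 and 88 for replicate 2. There was no second tissue, age or treatment, so the comparisons are those between the replicates and those between parts of the genome within the peak lists. Read numbers are not part of the peak lists, so the depth of each replicate is unknown. All positions are in mm10, and fold over control is the authors' own value for each peak.

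The authors listed 162260 peaks in replicate 1 and 167209 in replicate 2. The peaks were short, with a median width of 276 bp in replicate 1 and 312 bp in replicate 2, and covered 62.9 Mb and 77.1 Mb, or 2.38% and 2.91% of the sequenced genome. The median fold over control was 2.96 and 2.98. Of the replicate 1 peaks, 66.0% overlapped a replicate 2 peak by at least 1 bp, and of the replicate 2 peaks 58.0% overlapped one of replicate 1 (62.0% ± 5.69, SD, n = 2). Peaks placed at random on the same chromosomes overlapped in 5.60% and 5.24% of cases on average over 100 placements. The Jaccard index of the covered bases was 0.408, against 0.0154 for random placement. Stronger peaks, which were also wider, were shared more often. Among the 10% of peaks with the highest −log10 p, 98.2% of replicate 1 peaks and 97.4% of replicate 2 peaks were shared, and among the lowest 10% 42.1% and 33.7%. The median width was 746 and 970.5 bp in the former and 208 and 222 bp in the latter, and wider peaks overlap more readily. When the overlap had to reach 50% of both peaks, the shared percentage was 32.1% ± 0.682.

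The authors' replicated list held 98814 peaks, each also present in their pooled list, where they made up 46.4% of 212808 peaks on the chromosomes. These replicated peaks covered 77.1 Mb and had a median width of 584 bp and a median fold of 3.14. The pooled peaks left out of it had a median width of 226 bp and a median fold of 2.33. Of the replicated peaks, 83951 had a peak in both replicates, 5428 in replicate 1 only, 8955 in replicate 2 only and 480 in neither. A peak in both single lists was thus not required, since 14863 replicated peaks lacked one, and how these entered the list is not known. Across the 83951 peaks, the folds of the strongest overlapping peaks in the 2 replicates had a Spearman correlation of 0.474 and a Pearson correlation of 0.562. This correlation is across peaks, which are not independent replicates. The replicated list is the one described below unless a replicate is named.

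H3K4me1 was concentrated around transcription start sites (TSS) and in introns of protein-coding genes. Here the TSS of all basic protein-coding transcripts were counted. Within 1 kb of a TSS lay 14.1% of the replicated summits, 6.95 times the 2.03% of the genome in this class. A further 17.2% lay 1 to 5 kb from a TSS, 2.54 times the genome's share. Introns held 39.3% of the summits and 31.9% of the genome. Sequence outside protein-coding genes held 27.4% of the summits and 57.5% of the genome, a ratio of 0.476. In the replicates' own lists the promoter class held 11.7% ± 0.161 of the summits (SD, n = 2), and the class outside genes 28.4% ± 0.516. Each of these differences from the genome's share was far larger than the spread between replicates.

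At promoters rich in CpG dinucleotides, which belonged to 10072 of the 21851 protein-coding genes, the mark lay on both sides of the TSS and dipped at the TSS itself. A replicated peak covered 13.04% of these TSS, 27.4% of the positions 1 kb upstream and 57.9% of those 1 kb downstream. The TSS value was thus 29.6 percentage points below the mean of the flanking positions. In the replicates' own lists the difference was −22.5 and −28.6 points (−25.6 ± 4.27, SD, n = 2). The other 11779 promoters had the opposite shape. There 16.1% of TSS were covered, against 5.43% at 1 kb upstream and 13.8% at 1 kb downstream, a difference of 6.49 points (5.23 ± 0.222 in the replicates).

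**Figure D1:**
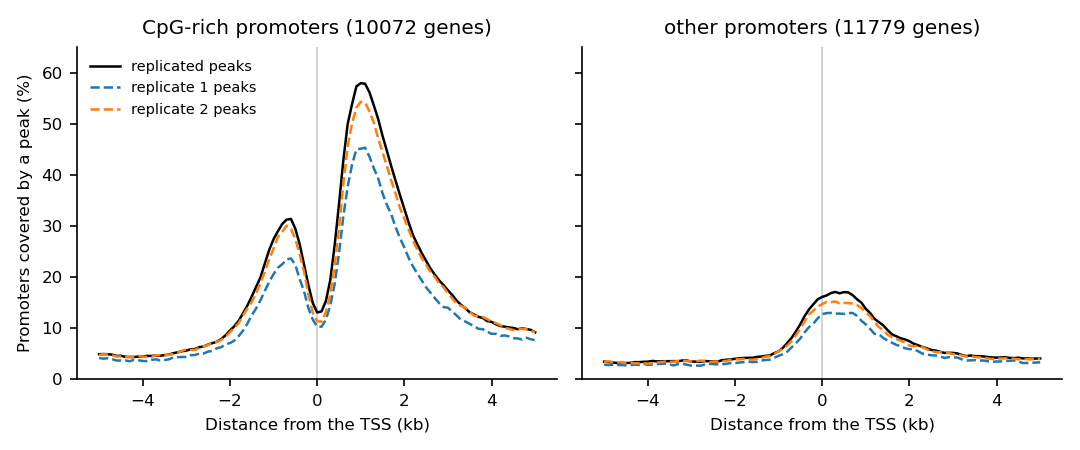
Percent of promoters covered by an H3K4me1 peak at each distance from the TSS (kb, transcription running to the right), for CpG-rich promoters on the left and other promoters on the right. Black lines show replicated peaks and dashed lines each replicate's own peaks. Coverage of CpG-rich promoters falls to 13.04% at the TSS between maxima of 31.3% upstream and 57.9% downstream, while other promoters peak at 17.1% just downstream of the TSS.

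To describe H3K4me1 around genes, the percent of the window from 50 kb upstream to 50 kb downstream of each TSS that replicated peaks covered was measured. The median over all protein-coding genes was 3.14%, and 4632 genes (21.2%) had no replicated peak in the window. Lists of genes fixed before the data were examined were set beside 10000 random lists of the same size, matched on the number of TSS in the window. A list was called above or below when its median lay in the highest or the lowest 2.5% of the random medians. Of the 29 lists, 17 were above and 2 below. With random lists matched on gene length or not matched, 10 were above, and with matching on the promoter's CpG class, a choice made after seeing the data, 11. These percentiles describe these peak lists and are not p-values, since genes are not replicates.

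Genes of neural progenitors and of dorsal patterning were among the most densely covered outside the Hox clusters. The median neural progenitor gene had 13.6% of its window covered, 4.32 times the median of all genes, and 11.1% ± 2.68 in the replicates (SD, n = 2). Of the 18 genes, 12 had more than 7.86%, the 75th percentile of all genes. Notch1, the receptor that keeps progenitors undifferentiated, had 46.3% (40.2% ± 2.91), and rank 32 among all genes. Its TSS lies on chromosome 2 at 26503822, and the strongest peak, at 26481659 to 26500693 with a fold of 6.75, had its summit in a Notch1 intron. Nes, which encodes the intermediate filament nestin, had 30.5% (28.6% ± 1.60). The progenitor factor Sox2 had 22.2% (16.6% ± 5.49, with 12.7% in replicate 1), with its strongest peak outside protein-coding genes on chromosome 3 at 34691244 to 34691981. The lowest member was Sox3 on the X chromosome, with 0.197% (0.470% ± 0.117). Of the 18 genes of dorsal patterning, 15 lay above the 75th percentile and the median was 13.2% (11.3% ± 1.97). Pax7, a transcription factor of dorsal progenitors, had 38.2% (31.6% ± 4.36), Lmx1b 28.1% (23.6% ± 0.591) and Pax3 24.0% (19.0% ± 8.49). For Pax3 the values of replicate 1 (12.99%) and replicate 2 (24.998%) were far apart. The lowest member was Atoh1 with 5.02%. Both lists lay at the 100th percentile.

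Ventral patterning genes had a median of 6.70% (5.95% ± 0.348) and percentile 99.8. Ptch1, the receptor of Sonic hedgehog, had 30.9% (27.5% ± 4.03), and its strongest peak was intronic, on chromosome 13 at 63523973 to 63529811. Irx3 had 14.5% (11.6% ± 3.14, with 9.34% in replicate 1) and Gli2, a transcription factor of the hedgehog pathway, 12.9% (12.9% ± 0.396). Foxa2, a floor plate factor, had no replicated peak in its window, and its coverage in the replicates' own lists was 0.862% ± 0.577. The transcription factors of spinal neuron subtypes had a median of 6.55% (5.82% ± 0.152) and percentile 99.9. The LIM homeobox genes Lhx3 and Lhx1 had 16.2% (12.1% ± 0.105) and 15.6% (13.3% ± 0.973), Lbx1 had 15.3% (13.4% ± 1.37), and Isl1, a factor of motor neurons, only 1.74% (1.02% ± 0.319, with 0.798% in replicate 2). Forebrain regulators had a median of 5.81% (5.09% ± 0.736) and percentile 99.5, with Dlx1 at 10.3% (8.86% ± 0.966), Dlx2 at 9.69% (8.32% ± 1.16), Eomes at 8.18% (7.69% ± 0.350) and the X-linked Arx at 1.38% (1.32% ± 0.892, with 0.689% in replicate 1). These 3 calls, of ventral patterning, spinal neuron subtypes and forebrain regulators, ended when the random lists were matched on gene length (percentiles 94.7, 95.2 and 85.4) or not matched (96.1, 97.1 and 91.9). They also ended with matching on CpG class (92.8, 89.5 and 82.1), and those of ventral patterning and forebrain regulators with windows of 100 kb on each side (94.4 and 92.2). The strongest peaks in the windows of Dlx1 and Eomes had their summits in Dlx2 and Golga4.

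The list of retinoic acid signalling and Hox cofactors had a median of 15.5%, 4.94 times that of all genes (12.99% ± 0.80 in the replicates), and 10 of its 12 genes lay above the 75th percentile. Rara, a retinoic acid receptor, had 42.8% (39.9% ± 1.49). Its strongest peak, in a Rara intron on chromosome 11 at 98969453 to 98971984, had a fold of 9.94. Crabp2, which encodes a retinoic acid binding protein, had 33.5% (31.4% ± 1.34) and the Hox cofactor Pbx1 31.9% (25.6% ± 4.10). The windows of Nes and Crabp2 overlap on chromosome 3, and their strongest peak is the same one, at 87929029 to 87929777 in the promoter class within the gene Rrnad1. Aldh1a2, which encodes an enzyme of retinoic acid synthesis, had the lowest value of the list with 2.69%. Pan-neuronal genes had a median of 4.30% (3.91% ± 1.15) and genes of later glia 5.41% (4.73% ± 1.15). Neither list stood apart from random lists, with percentiles 92.4 and 82.5, although the pooled list placed pan-neuronal genes above (98.1). Within them the neuronal splicing factor Rbfox3 had 25.4% (23.2% ± 2.36), Elavl3 17.2% (14.8% ± 4.405) and Stmn1 15.2% (13.2% ± 0.365), and Nrxn1 had 0.334%. The strongest peak in the Elavl3 window had its summit in Prkcsh. Among the glial genes Cspg4 had 14.7% (12.7% ± 0.970), Gfap 10.3% (9.01% ± 1.12) and Mbp 10.1% (9.91% ± 4.21), and the X-linked Plp1 had 0.354%.

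**Figure D2:**
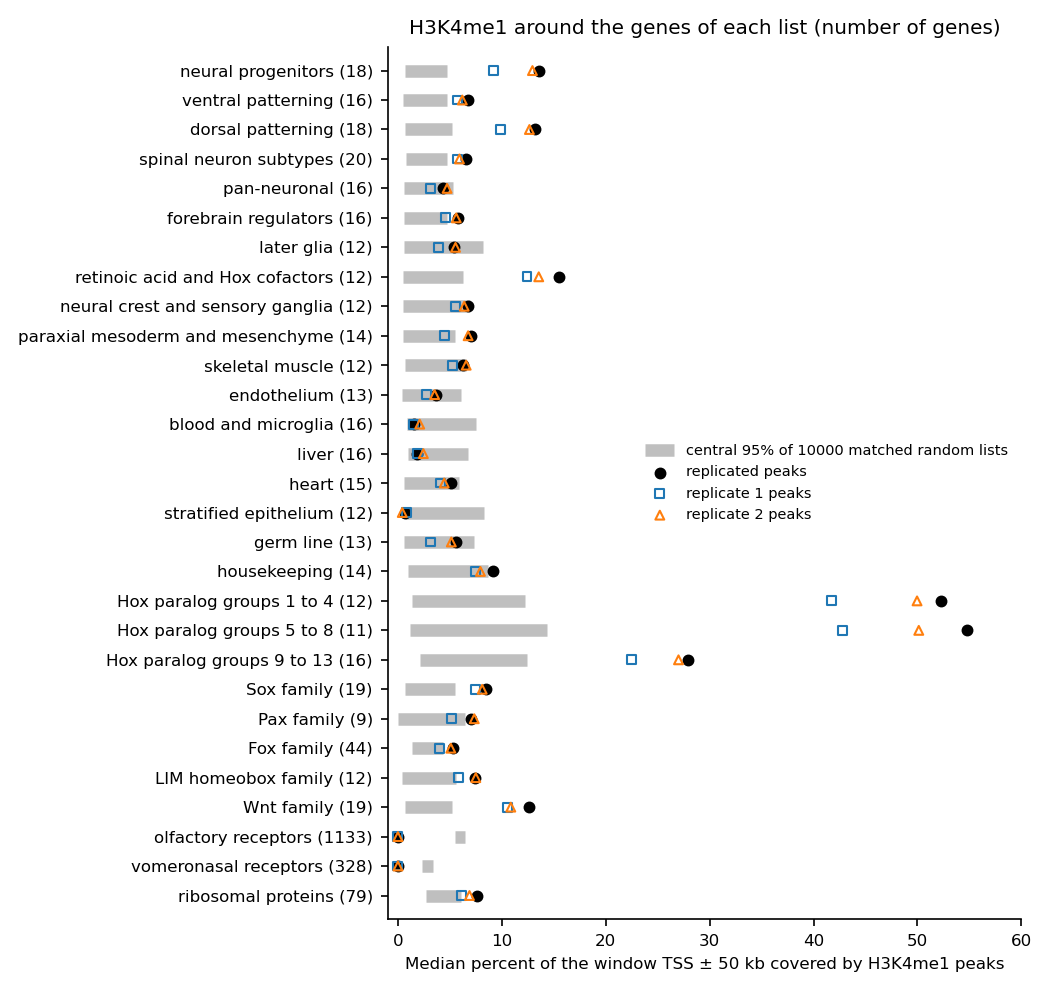
Median percent of the window TSS ± 50 kb covered by H3K4me1 peaks for each gene list, with the number of genes in brackets. Black points are replicated peaks, open squares and triangles the own peaks of replicates 1 and 2, and grey bars the central 95% of 10000 matched random lists for the replicated peaks. The Hox groups lie farthest to the right, at 52.3%, 54.8% and 27.9%, and the olfactory and vomeronasal receptors lie at 0.

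Of the 5 lists of other cell types that a dissected neural tube could hold, 1 was above random lists. Genes of paraxial mesoderm and mesenchyme had a median of 7.02% (5.63% ± 1.60, with 4.495% in replicate 1) and percentile 99.5, a call that ended with matching on gene length (96.4), without matching (96.3), with windows of 100 kb on each side (88.0) and with matching on CpG class (95.3). Tcf15 had 21.3% (17.8% ± 2.72), the cartilage collagen gene Col2a1 21.2% (17.4% ± 0.834), Tbx6 19.8% (16.9% ± 1.06) and Pax1 0.538% (1.25% ± 0.141). The strongest peak in the Tbx6 window lay in the promoter class within the neighbouring gene Ypel3. Neural crest and sensory ganglia had a median of 6.75% (5.95% ± 0.603) and percentile 97.05, with the crest factor Sox10 at 18.2% (14.7% ± 1.26), Prph at 17.4%, Ntrk1 at 15.1% and Snai2 at 0.639% (0.330% ± 0.212). Skeletal muscle had a median of 6.28% (5.90% ± 0.944) and percentile 96.5, with Tnnt3 at 24.5%, Des at 19.5%, Myod1 at 10.8% (7.57% ± 2.499) and Myf6 at 0.469% (0.743% ± 0.161). For Myod1 replicate 1 had only 5.80%. These 2 lists were not called, although some other settings placed them above. Endothelium (median 3.65%, percentile 79.4) and blood and microglia (1.57%, percentile 9.22) did not stand apart. Eng, an endothelial gene, had 15.8%, Esam 8.94% and Fli1 7.74%, and Erg had no replicated peak. Epor had 14.7%, Klf1 14.5% and Aif1 10.3%, and Itgam had none. For Prph, Tnnt3, Des, Eng, Esam, Epor, Klf1 and Aif1 the summit of the strongest peak lay within another gene.

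None of the 4 lists of tissues outside the neural tube was called, although some other settings placed heart above and stratified epithelium below. Liver genes had a median of 1.85% (percentile 12.3) and genes of stratified epithelium 0.707% (0.613% ± 0.271, percentile 2.76), while heart genes had 5.09% (4.28% ± 0.253, percentile 94.1) and germ line genes 5.56% (4.12% ± 1.44, percentile 90.2). For the germ line list replicate 1 alone had a median of 3.10% and percentile 66.9, and for stratified epithelium replicate 2 alone had 0.421%. Foxa3 had 11.7%, Hnf1a 9.68% and Tat 5.13%, and Serpina1a had no replicated peak. Among the heart genes Myl7 had 8.74%, Myh6 7.89% and Hand1 7.45%, and Actn2 had none. Grhl3 had 15.02%, Sfn 5.90% and Krt1 1.84% (2.66% ± 0.684), and Lor had none. Figla had 15.8%, Zp3 8.15% and Acr 8.13%, and Sycp1 had none. Apart from Grhl3, the strongest peak in the window of each of these genes that had one lay with its summit within another gene. The 14 housekeeping genes had a median of 9.13% (7.71% ± 0.333) and percentile 98.2, which became 94.9 with the pooled list and 96.6 without replicate 1. Rplp0 had 19.0%, Vcp 18.5% and Polr2a 16.5%, and the X-linked Pgk1 had none. For Vcp and Polr2a the summit of the strongest peak lay in Pigo and Slc35g3.

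Among the fixed gene families the Wnt, Sox, LIM homeobox, Pax, Fox and ribosomal protein genes were above random lists and both receptor families below. The median was 12.6% for the 19 Wnt genes (10.7% ± 0.218, percentile 100), 8.49% for the 19 Sox genes (7.78% ± 0.470, percentile 99.95), 7.40% for the 12 LIM homeobox genes (6.66% ± 1.19, percentile 99.7), 7.03% for the 9 Pax genes (6.26% ± 1.54, percentile 98.4) and 5.26% for the 44 Fox genes (4.53% ± 0.792, percentile 99.8). The calls of the LIM homeobox, Pax and Fox families ended with matching on gene length (95.4, 95.85 and 97.2), without matching (96.5, 92.1 and 96.985) and with matching on CpG class (90.3, 90.9 and 87.7). The Pax call also ended with windows of 100 kb on each side (95.5) and with the peaks of replicate 1 alone (97.49). Ribosomal protein genes had a median of 7.64% (6.49% ± 0.561, percentile 99.9). The medians of 1133 olfactory receptor and 328 vomeronasal receptor genes were 0 in the replicated list and in both replicates, below all random lists. No replicated peak lay in the window of 992 and 313 of them.

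The Hox genes, transcription factors that set position along the body axis and lie in 4 clusters, had the densest H3K4me1 of all lists. The median percent of the window covered was 52.3% (45.9% ± 5.79, SD, n = 2) for paralog groups 1 to 4, 54.8% (46.4% ± 5.21) for groups 5 to 8 and 27.9% (24.7% ± 3.22) for groups 9 to 13, and each lay at the 100th percentile. This held when the genes of a cluster counted as 1 locus. Of the 10 protein-coding genes with the highest coverage in the genome, 7 were Hox genes, led by Hoxc4 with 74.5% (63.0% ± 8.04), Hoxb5 with 69.4% (56.8% ± 6.57) and Hoxc5 with 64.0% (55.99% ± 6.25).

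Taken over all clusters, the genes of the low-numbered groups were covered most. From start to end of the annotated gene, members of groups 1 to 4 were covered over 68.6% of their length on average (58.0% ± 6.38 in the replicates), members of groups 5 to 8 over 55.2% (44.4% ± 7.98) and members of groups 9 to 13 over 20.0% (18.9% ± 1.53). The first and the last of these differed by far more than the spread between replicates, and all 3 had the same order in both replicates. In the Hoxa cluster Hoxa4 was covered over 94.0% (72.1% ± 4.85) and Hoxa6 over 94.9% (86.7% ± 6.33), against 13.9% (19.6% ± 11.4) for Hoxa9 and 11.7% (11.8% ± 4.98) for Hoxa10. In replicate 2 alone Hoxa9 had 27.7%. In the Hoxc cluster Hoxc4 was covered over 85.8% (74.7% ± 5.69) and Hoxc9 over 12.8% (15.3% ± 1.31). The order of neighbouring groups was not seen within each cluster. In the Hoxa cluster groups 1 to 4 and 5 to 8 had means of 75.4% (62.8% ± 13.97) and 76.6% (65.6% ± 9.90), a difference within the spread between replicates. In the Hoxb cluster groups 5 to 8 and 9 to 13 had 37.7% (28.0% ± 2.26) and 37.1% (32.8% ± 2.97). In the Hoxd cluster the single gene of groups 5 to 8, Hoxd8, had 16.5% (12.4% ± 7.59, with 7.08% in replicate 1) and groups 9 to 13 had 23.7% (21.002% ± 2.86). Hoxb8 had no covered base in the replicated list or in either replicate, whereas Hoxb9 was covered over 59.9% (51.0% ± 1.54) and Hoxd9 over 44.2% (34.99% ± 11.2, with 27.1% in replicate 1). The annotated spans of Hoxa3, Hoxc5 and Hoxd3 include neighbouring Hox genes, so their values are not independent of those.

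**Figure D3:**
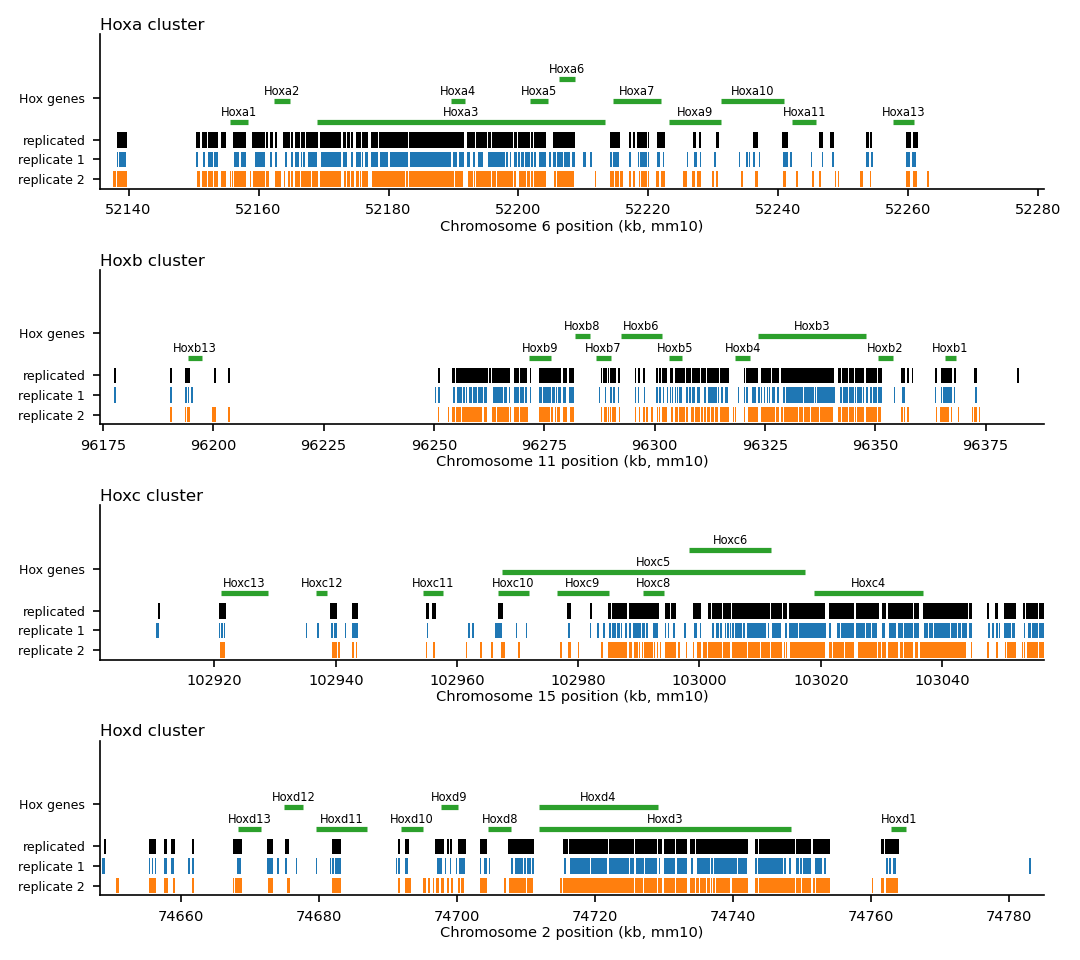
Positions (kb, mm10) of H3K4me1 peaks and Hox genes in the 4 Hox clusters. Black blocks are replicated peaks, blue and orange blocks the own peaks of replicates 1 and 2, and green bars the annotated genes. The longest domains of peaks run over Hoxa1 to Hoxa6, over Hoxc6 to Hoxc4 and over Hoxd4 and Hoxd3, while genes of groups 9 to 13 are covered over 20.0% of their length on average.

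Replicated peaks within 1 kb of each other merged into 64296 domains with a median length of 842 bp, of which 339 were at least 10 kb long. The 10 longest spanned 37.7 to 54.0 kb. The longest spanned 53996 bp at Ssbp3 (chromosome 4, 106912946 to 106966941), beginning 1476 bp from its TSS, and the last of the 10 (106967947 to 107005667) overlapped the same gene. The gap between these 2 domains was only just over the merging distance of 1000 bp, so their separation rests on that setting. The replicates' own peaks covered 73.9% ± 8.35 of the longest domain. When each replicate's own peaks were merged, the longest domain had 44534 bp in replicate 1 and 79876 bp in replicate 2. Ssbp3 encodes a binding partner of LIM domain cofactors. Of the 10 domains, 2 overlapped Gse1, at 120331299 to 120384543 and 120489934 to 120529615 on chromosome 8. The second of these held the highest fold of all replicated peaks, 10.4. Ccdc85c, Zmiz1 and Msi2, which encodes an RNA-binding protein of stem cells and progenitors, each overlapped 1 domain. The remaining 3 lay in the Hox clusters. They held the TSS of Hoxa1, Hoxa2, Hoxa4, Hoxa5 and 5730596B20Rik (52156136 to 52208653 on chromosome 6), of Hoxc6, Hoxc5 and Hoxc4 (103001455 to 103045014 on chromosome 15) and of Hoxd4 (74715423 to 74754090 on chromosome 2).

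The 500 longest domains held the TSS of 146 protein-coding genes. Members of the fixed symbol lists were 5.08 times as frequent among these as among all genes, 9 of 265 against 0.668% of genes (5.03 ± 0.443 in the replicates, SD, n = 2). With merging over 3 kb the ratio was 2.76. In the domains of replicate 1 alone no dorsal patterning or mesoderm gene had its TSS. Of the 39 Hox genes, 11 had their TSS in such a domain, a ratio of 42.2 (48.8 ± 6.38). The 9 genes came from the lists of neural progenitors (2), ventral patterning (2), dorsal patterning (2), retinoic acid and Hox cofactors (2) and paraxial mesoderm (1). In each replicate's own domains ventral patterning had only 1. Later glia had 1 in replicate 1, and retinoic acid and Hox cofactors had 3 in replicate 2. The other symbol lists, of neural and of other tissues alike, had none in the domains of replicated peaks. With 0.668% of all genes in these domains, most lists this short would have none, so this marks no difference between tissues.

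Short consensus sequences of transcription factors were counted in the peaks and in intervals of the same length, chromosome and GC content outside all pooled peaks. Of 20 consensus sequences, 16 had a ratio above 1 in the replicated list, and 10 reached at least 1.1 there and in both replicates. The NFI palindrome TTGGCNNNNNGCCAA had a ratio of 3.37 (4.67 ± 2.11 in the replicates, n = 2), but with only 175 matches in peaks and 52 in the matched intervals. In peaks beyond 5 kb of a TSS it was 5.42. The retinoic acid receptor element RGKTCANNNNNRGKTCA, a direct repeat, had a ratio of 1.87 (1.93 ± 0.134) and the SP/KLF box GGGCGGGG 1.86 (1.70 ± 0.0567). Homeodomain (TAATTA), octamer POU (ATGCAAAT) and RFX (GTTGCCA) sequences had ratios of 1.55 (1.58 ± 0.0257), 1.43 (1.40 ± 0.0303) and 1.30 (1.28 ± 0.0064). The proneural E-box CAGCTG had 1.24 (1.28 ± 0.0171), whereas CAGATG had only 1.03 (1.04 ± 0.01), and the SOX sequence ACAAAG had 1.18 (1.19 ± 0.0015). The muscle-associated MEF2 sequence CTATTTATAG had a ratio of 2.69 (2.53 ± 0.203) from 207 and 77 matches. The liver-associated HNF1 sequence had a ratio of 1.34 from only 39 matches in peaks and 29 in the intervals, with a wide spread between replicates (1.56 ± 0.413).

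Ratios near 1 were found for AP-1 (0.993), SRF (1.01) and TEAD (1.05). The CTCF core was less dense in peaks (0.930, and 0.911 ± 0.0236 in the replicates), as was the ETS sequence CCGGAAG (0.812, and 0.802 ± 0.0619). For GLI the replicated ratio of 0.945 and the replicates' mean of 1.02 ± 0.0720 lay on both sides of 1, and in peaks beyond 5 kb of a TSS it was 1.05. TCF/LEF had 1.11 (1.09 ± 0.0181), GATA 1.07 (1.08 ± 0.0082) and HNF4A 1.101, of which the replicates' own lists gave 1.00 ± 0.0328. Against flanks 5 to 10 kb away the ratio lay on the other side of 1 for 10 sequences. Among them were homeodomain (0.754), SOX (0.981), HNF1 (0.679), the CTCF core (1.27) and ETS (1.83). Of the sequences that did not cross 1, octamer POU fell to 1.003 and MEF2 to 1.16. NFI (3.86), SP/KLF (4.10), the E-box CAGCTG (1.72) and RFX (1.38) were higher than with matched intervals. These flanks had a GC content of 45.0% and not the 50.9% of the peaks.

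**Figure D4:**
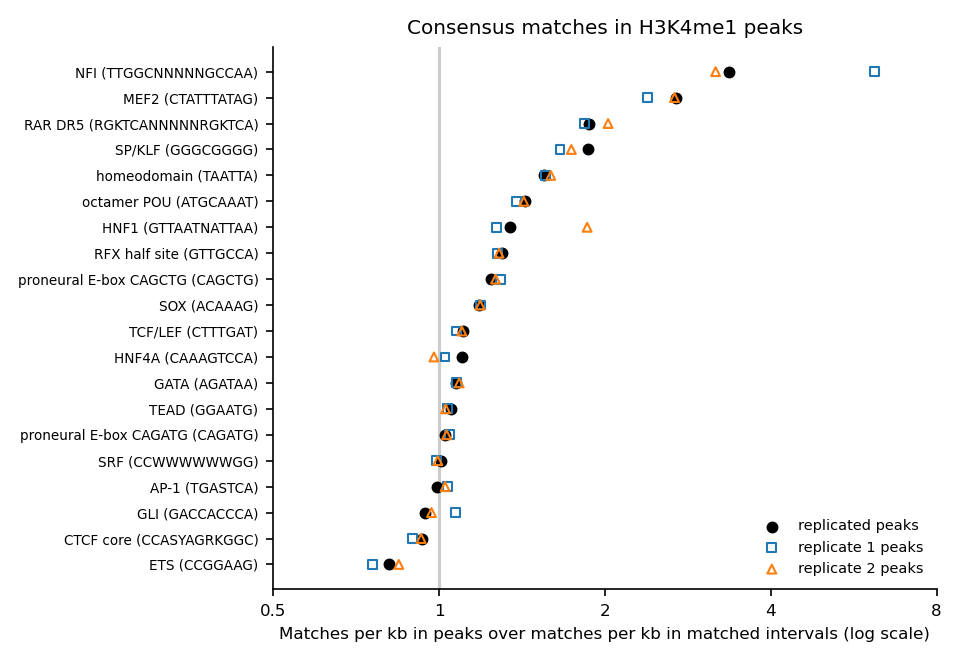
Matches per kb of each consensus sequence in H3K4me1 peaks divided by matches per kb in intervals of matched length and GC content (log scale), with black points for replicated peaks and open symbols for each replicate's own peaks. The ratios of the replicated list run from 0.812 for ETS to 3.37 for NFI, and the replicates lie far apart for NFI (6.17 and 3.18) and HNF1 (1.27 and 1.86).

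Peak density was uneven between chromosomes. The autosomes held 41.1 replicated peaks per Mb, between 28.2 and 66.5, and were highest on chromosome 11. The X chromosome held 395 replicated peaks, or 2.42 per Mb, which is 0.0588 of the autosomal density. In the replicates' own lists it was 0.0601 and 0.0797 (663 and 904 peaks), and with only the 50000 strongest peaks of each replicate 0.0282 and 0.0323. No peak of any list lay on the Y chromosome. The genes with the lowest coverage in the lists of neural progenitors, forebrain regulators, later glia and housekeeping were X-linked. With autosomal genes only, an alternative added after seeing the data, stratified epithelium was below random lists (percentile 1.55), and the Pax family lay just under the limit for a call (97.48). Neither list holds an X-linked gene, so only the random lists changed for them. The median of pan-neuronal genes, 2 of them X-linked, rose to 5.78% (percentile 97.01), and that of later glia, with 1, to 7.18% (91.65). Both remained without a call. Blood and microglia, with 2, stayed at 1.57%.

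**Figure D5:**
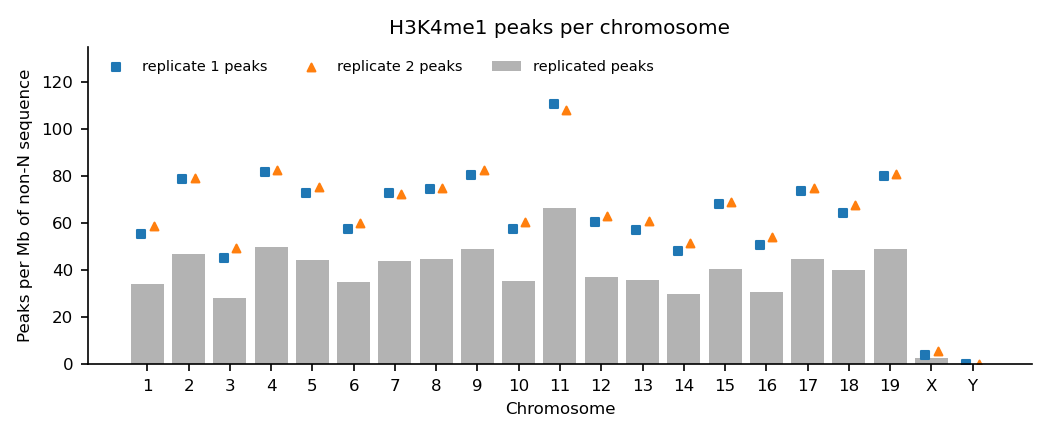
H3K4me1 peaks per Mb of sequenced bases on each chromosome, with bars for replicated peaks and symbols for each replicate's own peaks. The autosomes lie between 28.2 and 66.5 replicated peaks per Mb, the X chromosome at 2.42 and the Y chromosome at 0.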

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

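Chosen after seeing the result were the tests with replicated peaks that have a peak in both replicates, with matching on CpG class, with autosomal genes only, with peaks beyond 5 kb of a TSS, and the X chromosome values without each replicate. Of the 29 gene lists, 16 kept their call in each alternative: neural progenitors, dorsal patterning, later glia, retinoic acid and Hox cofactors, endothelium, blood and microglia, liver, germ line, the 3 Hox groups, the Sox and Wnt families, both receptor families and ribosomal proteins. No list went from above to below. Since read depth is unknown, how far depth limits the lists of weak peaks could not be measured. Leaving out 1 replicate puts the other replicate's own list, with shorter peaks, in place of the replicated list, so the values given for it change in both ways at once. No paired analysis was possible because there is a single group.

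The number of lists above random lists was 10 with matching on gene length, 10 without matching and 11 with matching on CpG class, against 17. With matching on gene length the percentile was 94.7 for ventral patterning, 95.2 for spinal neuron subtypes, 85.4 for forebrain regulators, 96.4 for mesoderm, 95.85 for Pax, 97.2 for Fox and 95.4 for LIM homeobox genes. Without matching these were 96.1, 97.1, 91.9, 96.3, 92.1, 96.985 and 96.5, and with matching on CpG class 92.8, 89.5, 82.1, 95.3, 90.9, 87.7 and 90.3. With windows of 100 kb on each side ventral patterning lay at 94.4, forebrain regulators at 92.2, mesoderm at 88.0 and Pax at 95.5, all no longer called, and skeletal muscle at 98.1, heart at 97.6 and stratified epithelium at 1.82, now called. With windows of 20 kb neural crest (98.0) and skeletal muscle (98.8) were above. With −log10 q of at least 5 skeletal muscle (97.7) was above and stratified epithelium (2.29) below. With the pooled list pan-neuronal genes (98.1) were above, stratified epithelium (1.68) below and housekeeping genes (94.9) not called. With the 50000 strongest peaks neural crest (97.6) and heart (98.1) were above and stratified epithelium (1.59) below. CpG class matching placed skeletal muscle at 97.9, and with autosomal genes only stratified epithelium lay at 1.55 and Pax at 97.48. Leaving out 1 replicate gave 96.8 to 97.8 for skeletal muscle, 0.945 to 4.32 for stratified epithelium, 96.6 to 98.3 for housekeeping genes and 97.49 to 98.7 for Pax. The causes of these changes were not tested.

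The shared percentage of replicate peaks was 49.9% when the overlap had to reach 50% of the peak and 32.1% when it had to reach 50% of both. The X chromosome's density relative to autosomes was 0.0303 with the 50000 strongest peaks and 0.0601 to 0.0797 leaving out 1 replicate. The promoter share was 24.6% within 2.5 kb, 13.8% for midpoints, 16.5% with −log10 q of at least 5, 9.98% in the pooled list, 14.95% for peaks present in both replicates and 11.6% to 11.8% leaving out 1 replicate. The TSS difference was −28.6 to −22.5 points leaving out 1 replicate at CpG-rich promoters. At other promoters it was 4.96 with −log10 q of at least 5, 7.72 in the pooled list, 5.86 for peaks in both replicates and 5.08 to 5.39 leaving out 1 replicate. The enrichment of fixed lists in the longest domains was 5.75 without merging over gaps and 2.76 with merging over 3 kb.

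With flanks in place of matched intervals the motif ratio lay on the other side of 1 for 10 sequences, SOX (0.981), homeodomain (0.754), TCF/LEF (0.859), GATA (0.741), HNF4A (0.979), SRF (0.920), ETS (1.83), CTCF (1.27), GLI (1.52) and HNF1 (0.679). Without crossing 1, octamer POU fell to 1.003 and MEF2 to 1.16, while SP/KLF rose to 4.10. The flanks were not matched on GC content, which was 45.0% against 50.9%. In peaks beyond 5 kb of a TSS the ratio was 5.42 for NFI and 1.05 for GLI. Leaving out 1 replicate gave 0.979 to 1.03 for HNF4A and 0.990 to 0.995 for SRF. Of 666 alternative values for the windows of named genes, 206 moved by less than the spread between replicates and 460 did not. The latter include unchanged values of Itgam and Serpina1a, whose replicates had no coverage and thus no spread.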

Other observations

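The families described here and the tests on the X chromosome were chosen after seeing the data, while the 2 tests on other cell types were written before their results were seen. Several families of signalling and regulatory genes had dense H3K4me1 around their TSS. The median percent of the window covered was 24.8% for the 6 Groucho corepressor genes (21.4% ± 1.01 in the replicates, SD, n = 2), 16.4% for the 22 ephrins and Eph receptors (14.02% ± 0.813), 15.1% for the 9 Notch receptors and ligands (13.4% ± 1.47), 9.75% for the 6 Iroquois genes (8.48% ± 1.71), 9.53% for the 11 Hedgehog and Gli genes (8.60% ± 1.36) and 6.79% for the 16 T-box genes (5.999% ± 0.40). Each was above random lists matched on TSS number, also with 1 gene per locus, while matching on gene length or CpG class was not run for these families. The Zic family (9.41%) and collagens (3.89%) were above at percentiles of 97.6 and 97.51, and no longer so with 1 gene per locus (95.03 and 96.5). Cytochromes P450 had a median of 0 and were below. Protocadherin clusters (median 0) and keratins (1.62%) were below, but not with 1 gene per locus (percentiles 4.58 and 8.09). Histone clusters (7.13%), Zfp genes (2.86%), Fgf (4.62%) and Bmp (2.62%) genes did not stand apart.

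The 7 replicated peaks with the highest fold lay in introns or near the TSS of Gse1 (fold 10.4), Rara (9.94), Ncor2 (9.54), Zfp423 (9.21) and, tied at 9.10, Chd3, Bahcc1 and Eif4g1. In the Hox clusters, widened by 20000 bp on each side, 5 of the 7 matches to the retinoic acid receptor element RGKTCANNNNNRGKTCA lay in replicated peaks. They were 3 of 3 in the widened Hoxa cluster, 1 of 3 in Hoxb and 1 of 1 in Hoxd. Peaks covered 42.0%, 36.9% and 39.0% of these widened clusters, and matches this few do not show an excess over that coverage. The matches in peaks include GGTTCACCGAAAGTTCA at 52153426 to 52153442 on chromosome 6, 4891 bp from the TSS of Hoxa1, GGTTCATAGAGAGTTCA at 96372776 to 96372792 on chromosome 11, 7024 bp from that of Hoxb1, and GGTTCAAGCAGAGTTCA at 74741540 to 74741556 on chromosome 2, inside Hoxd3. The interval 108000001 to 109000000 on chromosome 8 held 175 replicated peaks and none of the TSS chosen, 1 per protein-coding gene. Other transcript starts were not counted. Among these peaks was 1 of the 10 replicated peaks with the highest fold (8.997), with its summit in an intron of Zfhx3. The gene classes of the other peaks in the interval were not counted, so they may also lie within genes that reach into it.

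The X chromosome held few peaks, and the design has no groups by sex, so no biological explanation was tested against another group. Fewer genes cannot account for it, since X gene windows had 0.0773 times the coverage of autosomal windows matched on TSS number, and random autosomal lists gave 0.872 to 1.11. More masked repeat sequence around genes cannot either, with a ratio of 0.1027 to autosomal windows matched on masked sequence. Masked percent does not measure how well reads map, and sequence far from genes was not compared. Loss of reads to repeats was thus not tested. If fold scaled with copy number, 3 X copies per 4 of each autosome would leave X peaks as dense as autosomal peaks of correspondingly higher fold, but at the fold with the lowest ratio it was 0.1274 or less in both replicates. For 1 X copy with the mark per 2 of each autosome the ratio would be about 1. It ran from 1.2778 to 20.9, with a lowest 95% Poisson limit of 1.19 that treats peaks as independent. Fold is a ratio to the control, so a control that also changed with copy number would cancel part of the dose. For 1 copy per 2 such cancelling would put the ratio above 1, so that test cannot decide. For 3 copies per 4 it would likewise raise the ratio, yet the ratios ran from 0.127 to 0.2035 over both replicates and all folds tested. These values argue against 3 copies per 4 as the only cause, unless fold falls by more than the copy number does. Since how fold scales with dose is assumed and the authors' filtering of the X was not tested, the cause stays open.

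The replicates differed at some lists, most at Hox groups 5 to 8 (8.40 points more in replicate 2), 1 to 4 (7.86 points) and 9 to 13 (3.83 points, percentile 99.64), whose coverage exceeds that of the lists they were matched to. At dorsal patterning genes the median of replicate 2 minus replicate 1 was 3.30 points. The central 95% of lists matched on coverage ran from 0.881 to 2.413 there (percentile 99.99). The median was 2.26 at neural progenitors (matched lists 0.612 to 2.198, percentile 98.2) and 1.43 at pan-neuronal genes (0.23 to 1.374, percentile 98.3). Stratified epithelium hardly differed between the replicates (−0.009), and this lay below most of its matched lists (0 to 0.441, percentile 1.05). More mesenchyme or muscle in 1 replicate was neither shown nor excluded, with mesenchyme at percentile 2.66 and skeletal muscle at 26.11. More blood or vessel was not either, with endothelium at 29.82 and blood and microglia at 21.9. The bound set beforehand, that 1 list inside the random range speaks against the explanation, was too weak, since a value within that range excludes nothing, and differences in depth or dissection were not tested.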
